A study of Arabidopsis thaliana with 24 samples.

How the data were processed

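RNA was sequenced from aerial rosette tissue of Col-wt, 4 epiRILs and their 4 epiHybrids, grown in long days and harvested at 21 or 22 days after sowing, 24 libraries in 9 groups. RNA was extracted with Trizol and RNeasy columns, per the labels' protocols. Per the submitters' processing notes, Trimmomatic, TopHat, Cuffnorm and Cuffdiff were used with the TAIR10 genome; their versions, order and settings are not given in the sources used here. The authors deposited FPKM values per entry and library, with entries of the assembled-locus kind and 1 column per library. How the FPKM values were scaled between libraries is not given in the sources used here. A deposited table of line comparisons holds the authors' p-values and q-values for each pair of lines, in the columns of a Cuffdiff gene table per the file headers. The same deposited table gives the authors' log2 fold change, infinite where a line is at 0. From it only the number of significant entries and their direction were taken, and the largest q-value marked significant was 0.0499.

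FPKM divides reads by transcript length, so very short entries reach high values from few reads, and a few abundant entries change the sum of a library. No counts were used, so depth is unknown and no count model was run. An exact 0 can be a failed estimate, so a gene is only said to be listed at 0 where its libraries are at 0. Whether counting used the strand is not given in the sources used here, so reads of an entry and an antisense partner may not have been kept apart.

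Values were taken as log2(FPKM + 1), a pseudocount of 1, and fold changes are on this scale, which understates changes of low genes. Of 34205 entries, 5034 were at 0 in every library, and the 21038 with at least 1 FPKM in at least 2 libraries were tested. A linear model with all 9 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend, prior degrees of freedom 2.79), so all groups share an estimate of the spread. Calls have a Benjamini-Hochberg adjusted p under 0.05 over all entries of a comparison, two-sided. The 20 comparisons were 16 of single lines and 4 pooled ones with lines weighted equally. Errors of pooled comparisons come from the spread between libraries of a line, not between lines. The mid-parent comparison set the epiHybrid mean against log2 of the arithmetic mean of both back-transformed parent means, with a delta-method error from the same fit.

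Entry names were matched to RefSeq genes of a TAIR10 assembly by name: 28263 entries (82.6%) matched exactly 1 gene, 638 had no name, 1307 joined several genes and 2502 shared a name and chromosome with another entry. Of 25722 matches compared, 99.2% overlapped the RefSeq position. Coordinates are those of the deposited entries. The pseudogene class of the annotation (3851 entries, 848 tested) stood in for transposable element genes, which it does not list apart. That stand-in and the definition of active entries were set after the data were seen.

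The lists fixed in advance were DNA methylation machinery (27 tested members), auxin and shade growth (8), cell cycle and growth (21), circadian clock (17), cold and dehydration (13), floral organ markers (7), flowering time (14), glucosinolate synthesis (20), heat shock (9), iron homeostasis (10), jasmonate (20), loci known to be silenced by methylation (8), leaf senescence (10), light harvesting and chlorophyll (20), phosphate starvation (9) and salicylic acid defence (19). Root markers had 1 tested member and seed markers 0, so neither was tested as a list. Of 264 list genes 263 were matched, 11 of them to an entry joined with another gene. Lists were tested with camera in limma at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Of 255 such tests, the pseudogene class included, 87 passed, and 20 with an estimated correlation.

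The genes named were fixed by rule: for each single-line comparison the 3 largest positive and 3 largest negative log2 changes past the threshold, for each pooled one 5 each way, up to 4 members per described list with the smallest adjusted p, and DDM1, MET1, SDC, FWA, QQS and FLC. Unless stated otherwise, the calls of named genes given with levels held in every fit that left out 1 library. The comparisons, tests, lists, naming rule and most alternative settings were chosen before the data were examined. Chromosomal neighbours were tested with 10000 permutations of calls over tested entries, and shared calls were set beside 100 simulations of unchanged groups. Libraries of the same groups were split in other ways (all 10 splits for 3 against 3, 100 draws for larger designs). The axis is the first principal component of the deviations from the group means. The axis score projects each library on it after centring on the mean of all libraries, scaled by its SD. The score therefore also holds differences between groups.

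The procedure was run on data simulated from the tested entries, 200 changed at each of 3 sizes. At a log2 change of 0.5, 1 and 2 it called 9%, 55% and 90.5% for epiRIL 92, 9.5%, 68% and 94.5% for epiRIL 150, 24%, 77.5% and 96.5% for all epiRILs against Col-wt, 27.5%, 76.5% and 97% for epiHybrid 150 against its mid-parent and 64.5%, 94.5% and 98% for all mid-parents. Between 13 and 27 of 19838 unchanged entries were called. For a list of 20 planted genes camera in limma gave a p of 4.68e-26, and for an unchanged list 0.944.

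Alternative settings fixed in advance were a pseudocount of 0.1, no filter, rescaling by median ratios, limma array weights, the replicate number as a block, only the compared groups in the fit, a mid-parent on the log2 scale, line means as replicates, an estimated list correlation and leaving out each library in turn. After the data were seen, the axis score as a covariate, summed entries of the same name and a fit without mitochondrial and plastid entries were added. For array weights limma's default method did not converge, and its gene-by-gene method was used after both were run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for matching, positions and plots. SDC and FWA did not pass the filter and were not tested.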

Results

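RNA of Arabidopsis thaliana rosettes at 21 or 22 days after sowing was sequenced in 24 libraries from 9 groups. Col-wt, the Columbia wild type, had 3 libraries. The epigenetic recombinant inbred lines (epiRILs) 92 and 232 had 2 libraries each and epiRILs 150 and 193 had 3 each. The epiHybrid of epiRIL 92 and Col-wt had 2 libraries, and those of epiRILs 150, 193 and 232 with Col-wt had 3 each. epiRILs descend from a cross of a ddm1 mutant with wild type. DDM1 is a chromatin remodeller needed for DNA methylation and for transposon silencing, so the lines share nearly the same DNA sequence and differ in which stretches of each chromosome carry the methylation state of the mutant parent. Values were deposited as FPKM for 34205 entries without counts, so the sequencing depth is unknown. The FPKM values summed to between 922618 in epiRIL 193 replicate 3 and 2438124 in epiHybrid 232 replicate 3, where the single entry XLOC_019610 held 32.6% of the sum. Between 22530 entries in Col-wt replicate 1 and 26608 in epiRIL 92 replicate 1 were above 0. The lowest correlation of log2 values across entries between libraries of a group was 0.932 and the highest 0.984; entries are not independent replicates. The labels do not say that libraries came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

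Libraries of a group also differed among themselves. A single axis held 32.5% of the variance within groups. Its score was 1.13 and 1.06 in Col-wt replicates 1 and 2 and -1.01 in replicate 3, 2.06, 1.27 and -0.37 in the 3 epiHybrid 150 libraries, and -0.18, 2.08 and -0.8 in the 3 epiHybrid 193 libraries. It was 1.04, 0.98 and -0.87 in the 3 epiRIL 150 libraries and 0.8, -0.99 and -1.06 in those of epiRIL 193, so replicate 3 had the lowest score in each of these 5 groups. All libraries of lines 92 and 232 lay between -0.7 and -0.38. All 20 jasmonate genes and 95% of the 20 light harvesting genes had a positive slope on this score, with means of 0.42 and 0.37 on the log2 scale per SD, while the 7 floral organ markers all had a negative slope, with a mean of -0.19.

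The genes fixed in advance are given first. The entry of DDM1 (AT5G66750), which is joined with the neighbouring WAKL21 (chromosome 5, 26648951 to 26669951, TAIR10), so that its value is not that of DDM1 alone, stood at 12.4 ± 1.2 FPKM (SD, n = 3) in Col-wt and between 10.3 ± 1.02 (epiHybrid 92, n = 2) and 12.4 ± 1.7 (epiHybrid 150, n = 3) in the other groups, and no comparison called the joined entry. MET1 (AT5G49160), the maintenance CG methyltransferase, stood at 11.1 ± 3.55 FPKM in Col-wt and was called lower in epiHybrid 92 (6.19 ± 1.83, n = 2) with an adjusted p of 0.0442 from limma. The call was lost without the filter on low values, with only Col-wt and epiHybrid 92 in the fit, without epiHybrid 92 replicate 2 (adjusted p = 0.483) and without Col-wt replicate 1 or 2 (adjusted p = 0.185 or 0.175), and over all alternatives the adjusted p lay between 0.0003 and 0.483. Over the pooled epiHybrids MET1 fell by 0.51 on the log2 scale (SE 0.17, adjusted p = 0.0468). That call was lost without the filter, after rescaling, and without epiHybrid 92 replicate 2, epiHybrid 150 replicate 3, epiHybrid 193 replicate 1 or 3, any epiHybrid 232 replicate or Col-wt replicate 1 or 2 (adjusted p between 0.0547 and 0.327, and 8.87e-06 at the lowest over all alternatives). QQS (AT3G30720, chromosome 3, 12349040 to 12349905), a gene whose expression follows the methylation of repeats near it, was called lower in epiRILs 92 and 150 and higher in epiRILs 193 and 232. It stood at 8.93 ± 4.14 FPKM in Col-wt, at 0.372 ± 0.106 (n = 2) in epiRIL 92 and 1.13 ± 0.72 (n = 3) in epiRIL 150, but at 125 ± 37.3 (n = 3) in epiRIL 193 and 95.7 ± 4.44 (n = 2) in epiRIL 232. FLC (AT5G10140, chromosome 5, 3173497 to 3179448), the repressor of flowering that vernalization silences, stood at 2.15 ± 0.51 FPKM in Col-wt and was called lower in all 8 other groups, where means lay between 0.0791 (epiRIL 232) and 0.266 (epiHybrid 232) and 1 epiRIL 150 library was listed at 0. SDC stood between 0.0866 and 0.343 FPKM and was below the filter. FWA was listed at 0 in every library except 1 of Col-wt, at 0.0126 FPKM, and was not tested.

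**Figure D1:**
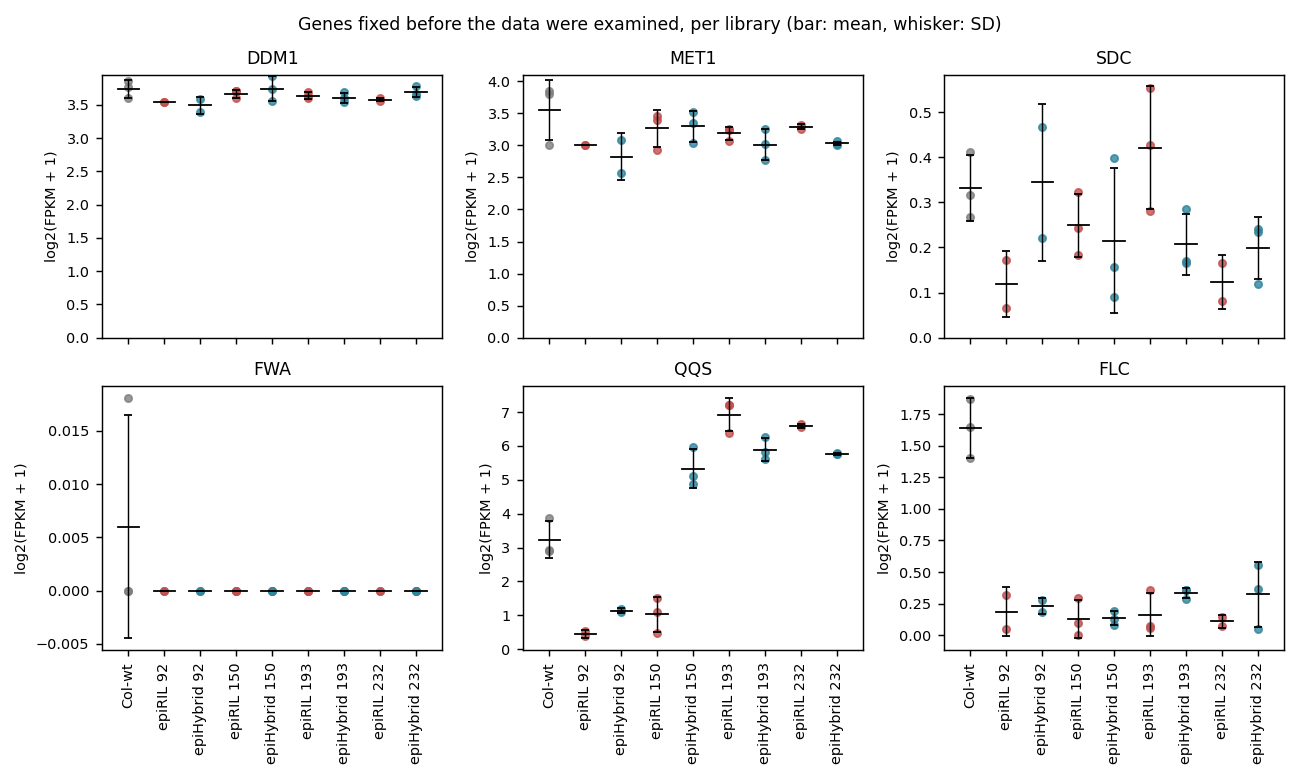
Each point is the log2(FPKM + 1) value of DDM1 (joined with WAKL21), MET1, SDC, FWA, QQS or FLC in 1 library, with the mean and SD of each of the 9 groups. QQS lies below Col-wt in epiRILs 92 and 150 and above it in epiRILs 193 and 232, and FLC lies below Col-wt in all lines and epiHybrids.

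Each epiRIL was compared with Col-wt to ask which transcripts changed in a line that carries part of the epigenome of the ddm1 parent. Entries of the pseudogene class were over-represented among those that rose. Entries that the annotation classes as pseudogenes, under which it lists transposable element genes, made up 4.03% of the entries tested. They made up 45.7% of those higher in epiRIL 92 (506 of 1107), 38.3% in epiRIL 150 (299 of 780), 35.0% in epiRIL 193 (430 of 1227) and 32.3% in epiRIL 232 (676 of 2090). In epiRIL 232, 79.7% of the 848 tested entries of the class were called higher. An entry silent in Col-wt passed the filter only where libraries of the lines or epiHybrids expressed it. The filter therefore favours higher calls of the class, here and in the epiHybrids, and raises the shares and odds ratios by an amount not tested. VANA21 and VANC21, genes of a VANDAL21 transposon on chromosome 2, were near or at 0 in Col-wt and reached 7.61 ± 0.306 and 3.17 ± 0.00573 FPKM in epiRIL 92 (n = 2). EVD, a copia retrotransposon listed under AT5G17125, rose from 0.0101 ± 0.00881 to 5.63 ± 1.35 FPKM in epiRIL 92, 10.2 ± 4.83 (n = 3) in epiRIL 193 and 6.87 ± 0.738 (n = 2) in epiRIL 232. CAC1 (AT2G12210), a CACTA transposon, was called in epiRIL 232 at 4.42 ± 0.104 FPKM (n = 2) against 0.00272 ± 0.00471 in Col-wt, and its mean was at most 0.00595 in the other epiRILs. The enrichment of the class among higher calls gave odds ratios between 22.3 and 52.2 in the 4 epiRILs and between 13.7 and 54.3 in the epiHybrids (two-sided Fisher's exact test against all tested entries, largest nonzero p 1.42e-224). As a list the class was higher in each epiRIL with an estimated correlation too, with adjusted p between 2.47e-05 and 0.0054.

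In all, limma called 1221 entries in epiRIL 92 (1107 higher, 114 lower), 911 in epiRIL 150 (780, 131), 1665 in epiRIL 193 (1227, 438) and 3416 in epiRIL 232 (2090, 1326) at an adjusted p under 0.05. Of these, 197 were called higher and 17 lower in all 4 epiRILs. The count depended on the wild-type libraries. Without Col-wt replicate 3 it was 2125 in epiRIL 92, 3394 in epiRIL 193 and 5850 in epiRIL 232. Without Col-wt replicate 1 or 2 it was 1071 or 1048 in epiRIL 193 and 2165 or 2095 in epiRIL 232. Leaving out epiRIL 232 replicate 1 or 2 left 1754 or 1952 calls there.

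**Figure D2:**
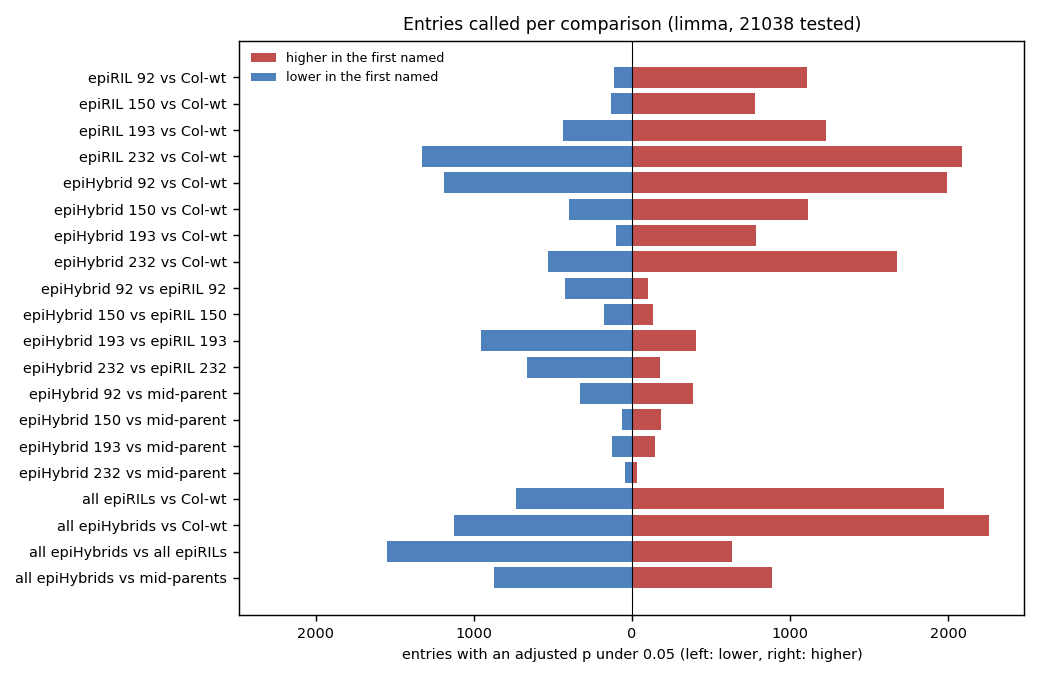
Bars give the number of entries called higher and lower at an adjusted p under 0.05 in each of the 20 comparisons of lines, pooled groups and mid-parents. In the comparisons with Col-wt the higher calls outnumber the lower ones.

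In epiRIL 92 the largest changes were in single loci. AT2G11778 (chromosome 2, 4727474 to 4732991) was listed at 0 in Col-wt and reached 2098 ± 176 FPKM (n = 2), and the unnamed entries XLOC_024124 (chromosome 4, 3839822 to 3839925) and XLOC_033889 (chromosome 5, 11321725 to 11321823), listed at 0 in Col-wt, reached 1055 ± 347 and 1657 ± 3.75. Both are very short, so few reads give a high FPKM. IRE1B (AT5G24360, chromosome 5, 8316440 to 8319981), a sensor of unfolded proteins in the endoplasmic reticulum, fell from 7.74 ± 0.508 FPKM in Col-wt to 0.0111 ± 0.0131, a log2 change of -3.11 ± 0.14 (SE, adjusted p = 3.08e-12). JAL5, a jacalin-related lectin (chromosome 1, 19333159 to 19336115), fell from 13.8 ± 3.73 to 0.753 ± 0.0786 FPKM, and AT2G34655 (chromosome 2, 14596631 to 14597540) from 44.1 ± 13.9 to 4.19 ± 0.438. QQS fell by 2.78 on the log2 scale (SE 0.35, adjusted p = 1.02e-05) and FLC by 1.45 (SE 0.16, adjusted p = 1.69e-06). Of the 8 loci known to be silenced by methylation, 4 rose and 2 fell, the same numbers as adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0611).

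In epiRIL 150 the same short entries XLOC_033889 and XLOC_024124 reached 2540 ± 809 and 1362 ± 193 FPKM (n = 3), and XLOC_021041 (chromosome 3, 15712777 to 15712871) reached 2845 ± 1034 against 7.06 ± 12.2 in Col-wt. AT2G11778 stood at only 2.29 ± 1.98 FPKM. VANC21 and VANA21 rose to 3.19 ± 0.807 and 2.96 ± 0.757 FPKM. TOC1 (AT5G61380) and BOA (AT5G59570), clock genes that peak in the evening, fell by 0.72 (SE 0.1, adjusted p = 4.08e-05) and 0.74 (SE 0.15, adjusted p = 0.00466) on the log2 scale, while the 17 clock genes as a list did not pass in any comparison (lowest adjusted p 0.346). QQS fell by 2.21 (SE 0.32, adjusted p = 7.98e-05) and FLC by 1.51 (SE 0.14, adjusted p = 3.42e-07). Of the loci silenced by methylation, 3 rose and 1 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.0814).

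In epiRIL 193 the 7 floral organ markers rose, as did 7 of 21 cell cycle and growth genes, while 7 of 19 salicylic acid defence genes fell, and each list lost the threshold with an estimated correlation. All 7 floral markers also rose adjusted over the list alone (list adjusted p = 7.31e-07; adjusted p = 0.146 with an estimated correlation). AG, AP1, SEP2 and SEP3, MADS-box genes of floral organ identity, stood at 2.71 ± 0.395, 7.32 ± 1.61, 3.9 ± 1.14 and 10.6 ± 2.38 FPKM (n = 3) against 0.431 ± 0.198, 1.07 ± 0.493, 0.405 ± 0.316 and 1.36 ± 1.48 in Col-wt. SPL9 and FUL, which promote flowering, rose by 1.39 (SE 0.2, adjusted p = 5.49e-05) and 1.91 (SE 0.3, adjusted p = 0.000157) on the log2 scale. Of 21 cell cycle and growth genes 7 rose (9 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0027, adjusted p = 0.146 with an estimated correlation). Among them were the mitotic cyclin CYCB1;1, from 2.04 ± 1.07 to 5.27 ± 0.393 FPKM, and the growth coactivator GIF1, from 12.3 ± 1.68 to 25.8 ± 1. Of 19 salicylic acid defence genes 7 fell (15 adjusted over the list alone; list adjusted p = 4.92e-09, adjusted p = 0.176 with an estimated correlation). The glucanase PR2 fell from 1416 ± 530 to 265 ± 51 FPKM, the thaumatin-like PR5 from 1945 ± 1189 to 279 ± 105, and FMO1, which makes the immune signal N-hydroxypipecolic acid, from 4.43 ± 1.73 to 0.487 ± 0.108.

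Single loci changed in epiRIL 193 too. MRD1 (AT1G53480, chromosome 1, 19963047 to 19974393) fell from 38.7 ± 1.49 FPKM to 0.345 ± 0.227, a log2 change of -4.9 ± 0.18 (SE, adjusted p = 2.3e-13). AT3G29633 (chromosome 3, 11452942 to 11453037), listed at 0 in Col-wt, reached 1419 ± 414 FPKM, and AT2G11778 reached 2524 ± 342. MAM3, a methylthioalkylmalate synthase of glucosinolate synthesis, fell from 11.2 ± 2.15 to 2.82 ± 0.409 FPKM, and VSP1, a jasmonate-induced storage protein with more than 1 entry of its name, rose from 38.8 ± 7.8 to 283 ± 199. The small heat shock gene HSP18.2 rose from 2.76 ± 1.2 to 7.54 ± 0.762 FPKM. Of the loci silenced by methylation 5 rose, 5 also adjusted over the list alone (list adjusted p = 1.18e-06, adjusted p = 0.00897 with an estimated correlation). Of 10 leaf senescence genes 1 fell (2 adjusted over the list alone; list adjusted p = 0.0313, adjusted p = 0.146 with an estimated correlation).

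In epiRIL 232, 15 of 19 salicylic acid defence genes were called lower (18 adjusted over the list alone; list adjusted p = 3.4e-11, adjusted p = 0.334 with an estimated correlation). PR2 stood at 75.7 ± 34 FPKM (n = 2), PR5 at 69.9 ± 21.5, WRKY38 at 2 ± 0.109 against 18.3 ± 6.45 in Col-wt, and ALD1, which makes pipecolic acid, at 0.828 ± 0.402 against 22.4 ± 15.7. Outside the list, the chitinase CHI (AT2G43570, chromosome 2, 18076224 to 18077463) fell from 351 ± 150 to 13.2 ± 9.32 FPKM, AT4G10500 (chromosome 4, 6491017 to 6492476), a salicylic acid hydroxylase, from 179 ± 104 to 4.68 ± 2.1, and the senescence-associated SAG13 from 87 ± 43.2 to 5.14 ± 1.69. PORC, a chlorophyll synthesis enzyme, rose from 157 ± 6.56 to 256 ± 14.2 FPKM and TOC1 fell from 29.4 ± 1.13 to 20.3 ± 0.539. The transposons CAC1 and AtMu1 rose (adjusted p = 1.22e-12 and 0.000316), AtMu1 to 1.11 ± 0.296 FPKM from a listed 0. Of the loci silenced by methylation 4 rose and 1 fell, as adjusted over the list alone (list adjusted p = 0.0481, adjusted p = 0.335 with an estimated correlation). The 20 jasmonate genes were lower as a list, with 0 members called by limma, 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.0481, adjusted p = 0.875 with an estimated correlation). All 20 had a positive slope on the axis score, and with this score as a covariate the jasmonate list did not pass (adjusted p = 0.356), nor did the loci silenced by methylation (adjusted p = 0.0649).

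Salicylic acid defence was also lower as a list in epiRIL 150 (0 members called by limma, 5 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone; list adjusted p = 8e-07, adjusted p = 0.598 with an estimated correlation) but not in epiRIL 92 (list adjusted p = 0.382). Floral organ markers were higher as a list in epiRIL 92 (0 called by limma, 6 at an unadjusted p under 0.05 and 5 adjusted over the list alone; list adjusted p = 0.0238, adjusted p = 0.678 with an estimated correlation). They were also higher in epiRIL 150 (0 called by limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone; list adjusted p = 0.0264, adjusted p = 0.817 with an estimated correlation). In epiRIL 232 the list missed the threshold (1 called, 7 adjusted over the list alone; list adjusted p = 0.0577). Light harvesting genes were higher as a list in epiRIL 150 (1 called, 2 adjusted over the list alone; list adjusted p = 0.0206, adjusted p = 0.817 with an estimated correlation). With the axis score as a covariate the floral list did not pass in epiRIL 92 (adjusted p = 0.0653). The 27 genes of DNA methylation were slightly lower as a list in epiRILs 92, 150 and 232, with medians of -0.26, -0.16 and -0.23 on the log2 scale (list adjusted p = 0.00458, 0.0449 and 0.0481; adjusted p = 0.678, 0.817 and 0.728 with an estimated correlation), and in epiRIL 232 they did not pass with the axis score as a covariate (adjusted p = 0.0904). Limma called 0, 0 and 1 members, with 7 and 3 at an unadjusted p under 0.05 in epiRILs 92 and 150, and 0 adjusted over the list alone in each. With only Col-wt and the epiRIL in the fit, limma no longer called QQS in epiRIL 150, PR5, VSP1, HSP18.2 and CYCB1;1 in epiRIL 193, or ALD1 in epiRIL 232.

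With the 10 epiRIL libraries pooled against Col-wt, limma called 2712 entries, 1977 higher and 735 lower. VANA21, VANC21, EVD and CAC1 rose with log2 changes of 1.88, 1.54, 2.48 and 0.61. SPL9, FUL and AG rose, and the flowering repressors FLC and MAF4 (an entry joined with AT5G65080), the defence genes PR2, PR5 and FMO1, MAM3, SAG13, TOC1 and BOA fell. Of the salicylic acid defence genes 8 fell (14 adjusted over the list alone; list adjusted p = 3.58e-08, adjusted p = 0.407 with an estimated correlation). Of the floral organ markers 6 rose (7 adjusted over the list alone; list adjusted p = 0.00112, adjusted p = 0.438 with an estimated correlation). Loci silenced by methylation rose (5 called, 5 higher and 1 lower adjusted over the list alone; list adjusted p = 0.000304, adjusted p = 0.0527 with an estimated correlation). Genes of DNA methylation were lower (1 called, 0 adjusted over the list alone; list adjusted p = 0.00865, adjusted p = 0.483 with an estimated correlation). Without Col-wt replicate 1, 2 or 3 the count was 1597, 1547 or 5336.

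Entries active in an epiRIL were mapped along the chromosomes. Counted as active were entries of at least 1 FPKM in every library of a group and under 0.1 in every Col-wt library: 749 in epiRIL 92, 373 in epiRIL 150, 530 in epiRIL 193 and 960 in epiRIL 232. In epiRIL 92, 12 of them lay on chromosome 3, against 154, 184, 193 and 205 on chromosomes 1, 2, 4 and 5. In epiRIL 150, 8 lay on chromosome 2, and in epiRIL 193, 11 on chromosome 1 and 19 on chromosome 5 but 171 each on chromosomes 2 and 3. In epiRIL 232 each chromosome held between 158 and 227. Neighbouring entries were called in the same direction, higher or lower, more often than after shuffling positions, with ratios of 9.61, 9.56, 5.84 and 3.19 in epiRILs 92, 150, 193 and 232 and 2.39, 4.52, 9.02 and 4.53 in their epiHybrids (10000 permutations, p = 0.0001 each, the smallest they can give). Among the 784 pseudogene-class entries used for this test alone, with higher calls only, the ratios were 1.39, 2.03, 1.56 and 1.08 in the epiRILs (permutation p = 0.0001 each, the smallest they can give).

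**Figure D3:**
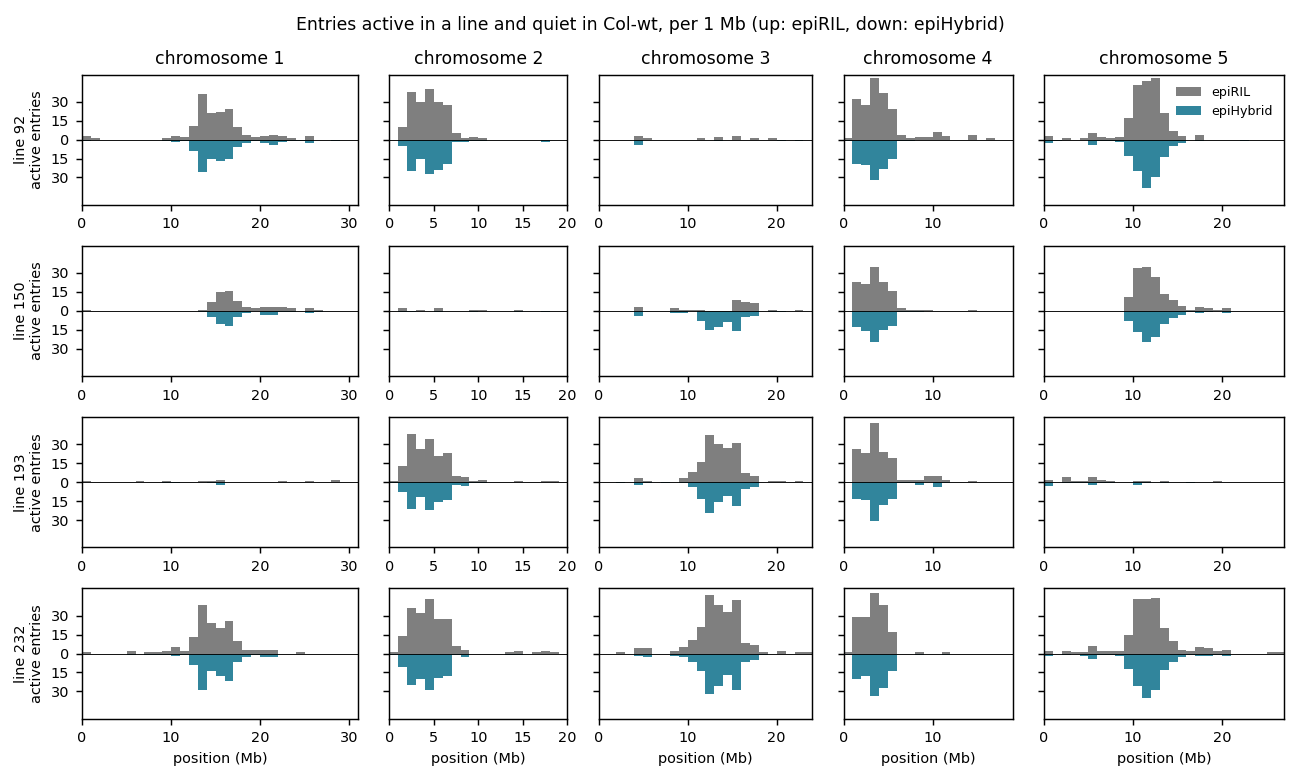
Bars give active entries per 1 Mb along chromosomes 1 to 5 (positions in Mb), upward for the epiRIL and downward for the epiHybrid of each of the 4 lines. epiRIL 92 has few on chromosome 3, epiRIL 193 few on chromosomes 1 and 5, and epiHybrid 150 carries 34 entries on chromosome 3 that are active in neither of its parents.

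Each epiHybrid was compared with Col-wt to ask what remained changed after a cross back to wild type. Different named transposon genes were called higher in different epiHybrids: VANA21 and VANC21 in epiHybrids 92, 150 and 193, EVD in epiHybrids 92, 193 and 232 and CAC1 in epiHybrid 232. Of 13 cold and dehydration genes 4 to 7 rose in each epiHybrid, and 1 fell in epiHybrid 232. VANA21 stood at 3.05 ± 0.929 FPKM (n = 2) in epiHybrid 92, 0.986 ± 0.337 (n = 3) in epiHybrid 150 and 1.92 ± 0.602 (n = 3) in epiHybrid 193. EVD stood at 3.81 ± 0.221, 3.69 ± 1.73 and 4.32 ± 1.16 FPKM in epiHybrids 92, 193 and 232, and CAC1 at 2.01 ± 0.384 in epiHybrid 232. AT2G11778 reached 791 ± 27.4, 1343 ± 132 and 767 ± 261 FPKM in epiHybrids 92, 193 and 232 and was listed at 0 in all 3 epiHybrid 150 libraries. The pseudogene class made up 22.6% of the higher calls in epiHybrid 92 (451 of 1993), 31.3% in epiHybrid 150 (348 of 1112), 43.1% in epiHybrid 193 (338 of 784) and 37.8% in epiHybrid 232 (634 of 1678). As a list it was higher in each, with adjusted p between 4.34e-05 and 0.00986 with an estimated correlation.

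Limma called 3185 entries in epiHybrid 92 (1993 higher, 1192 lower), 1510 in epiHybrid 150 (1112, 398), 888 in epiHybrid 193 (784, 104) and 2210 in epiHybrid 232 (1678, 532). Of these, 201 were called higher and 38 lower in all 4. Without epiHybrid 92 replicate 2 its count was 952, and without Col-wt replicate 1, 2 or 3 it was 1552, 1529 or 5555. For epiHybrid 150 the count was 931 without its replicate 1, 2733 without its replicate 3 and 907 or 867 without Col-wt replicate 1 or 2. It was 1387 for epiHybrid 193 without Col-wt replicate 3, and 1403, 1345 or 4688 for epiHybrid 232 without Col-wt replicate 1, 2 or 3.

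The cold and dehydration list passed as higher than in Col-wt in all 4 epiHybrids, but with an estimated correlation only in epiHybrid 193. In epiHybrid 92 it did not pass with the axis score as a covariate (adjusted p = 0.0959) or with the replicate number as a block. COR15A (AT2G42540) and COR15B (AT2G42530), chloroplast proteins that protect membranes in freezing, stood at 98.2 ± 83.4 and 191 ± 127 FPKM in Col-wt and at 805 ± 324 and 813 ± 166 in epiHybrid 193, 588 ± 291 and 645 ± 224 in epiHybrid 150, and 934 ± 351 and 623 ± 138 in epiHybrid 232 (n = 3 each). The pair of genes is listed on the same span (chromosome 2, 17704832 to 17712330), so reads could be shared between them. The galactinol synthase GOLS3 rose from 3.1 ± 0.901 to 19.8 ± 10 FPKM in epiHybrid 150 and 13.4 ± 4.25 in epiHybrid 193, RD29A from 60.3 ± 6.97 to 138 ± 30.9 and 169 ± 61.3, and KIN1 from 6.08 ± 2.99 to 24.9 ± 9.23 in epiHybrid 232. With Col-wt and the epiHybrid alone in the fit, limma no longer called COR15A, COR15B, GOLS3 or RD29A in epiHybrids 150 and 193, nor COR15B and KIN1 in epiHybrid 232. Of the 13 genes, 4 rose in epiHybrid 92 (5 adjusted over the list alone; list adjusted p = 0.0385, adjusted p = 0.685 with an estimated correlation) and 5 in epiHybrid 150 (9 adjusted over the list alone; list adjusted p = 2.16e-05, adjusted p = 0.131 with an estimated correlation). In epiHybrid 193, 7 rose (11 adjusted over the list alone; list adjusted p = 5.69e-09, adjusted p = 0.0238 with an estimated correlation). In epiHybrid 232, 5 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.00317, adjusted p = 0.46 with an estimated correlation).

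Some defence genes fell in 3 of the 4 epiHybrids. In epiHybrid 232 PR2, PR5, ALD1 and FMO1 stood at 219 ± 119, 163 ± 80.8, 1.77 ± 0.886 and 0.637 ± 0.379 FPKM (n = 3), CHI at 23.7 ± 16.3 and SAG13 at 10.1 ± 3.72. There 6 of the 19 salicylic acid defence genes were called lower (7 adjusted over the list alone; list adjusted p = 5.23e-06, adjusted p = 0.46 with an estimated correlation). In epiHybrid 92, 8 fell (14 adjusted over the list alone; list adjusted p = 4.16e-07, adjusted p = 0.546 with an estimated correlation). Among them PR2 stood at 288 ± 161 FPKM and PR5 at 262 ± 87.7 (n = 2), and without epiHybrid 92 replicate 2 their adjusted p was 0.108 and 0.115. With only Col-wt and the epiHybrid in the fit PR2, PR5, QQS and FRO3 in epiHybrid 92, QQS in epiHybrid 150 and ALD1 in epiHybrid 232 were no longer called. Over all alternatives the adjusted p in epiHybrid 92 lay between 0.000253 and 0.128 for PR2 and between 5.06e-05 and 0.187 for PR5. In epiHybrid 150, 2 fell (5 adjusted over the list alone; list adjusted p = 9.72e-05, adjusted p = 0.534 with an estimated correlation). In epiHybrid 193 limma called 0 members, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.00314, adjusted p = 0.839 with an estimated correlation).

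Single chloroplast, growth and glucosinolate genes changed in epiHybrids 92, 150 and 232. In epiHybrid 150 LHCB2.3, a light-harvesting protein, rose from 546 ± 95.7 to 2201 ± 852 FPKM (n = 3), PORC from 157 ± 6.56 to 220 ± 15.1, and the growth-promoting transcription factors PIF4 and PIF5 from 59.1 ± 3.6 to 86.4 ± 5.69 and from 40.7 ± 2.6 to 58.1 ± 2.17. These 4 calls were lost with only Col-wt and epiHybrid 150 in the fit. Light harvesting genes were higher as a list in epiHybrid 150 (3 called, 12 higher and 1 lower adjusted over the list alone; list adjusted p = 5.37e-05, adjusted p = 0.534 with an estimated correlation). They were higher in epiHybrid 92 too (2 called, 2 adjusted over the list alone; list adjusted p = 0.048, adjusted p = 0.794 with an estimated correlation). Of these 20 genes 95% had a positive slope on the axis score, so passing with it as a covariate in both epiHybrids decides nothing. With the replicate block the list did not pass in epiHybrid 92 (adjusted p = 0.21). In epiHybrid 92 TOC1 fell from 29.4 ± 1.13 to 15.4 ± 2.21 FPKM (n = 2), and the iron reductase FRO3 from 10.6 ± 1.35 to 5.64 ± 0.302, while the 10 iron homeostasis genes passed as a list in no comparison (lowest adjusted p 0.386). In epiHybrid 232 MAM3 and MYB28, a regulator of glucosinolate synthesis, fell to 5.17 ± 0.814 and 40 ± 2.9 FPKM from 11.2 ± 2.15 and 59.7 ± 3.61. There 4 of 20 glucosinolate genes fell, as adjusted over the list alone (list adjusted p = 0.000559, adjusted p = 0.46 with an estimated correlation), and in epiHybrid 92 1 fell (0 adjusted over the list alone; list adjusted p = 0.0283, adjusted p = 0.696 with an estimated correlation and 0.234 with the axis score as a covariate). JAL5 fell to 0.881 ± 0.312 FPKM in epiHybrid 150.

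Loci silenced by methylation rose in epiHybrid 150 (3 called, 3 adjusted over the list alone; list adjusted p = 0.00374, adjusted p = 0.131 with an estimated correlation) and in epiHybrid 193 (4 and 4 adjusted over the list alone; list adjusted p = 3.98e-05, adjusted p = 0.0238 with an estimated correlation). They rose in epiHybrid 232 (3 and 4 adjusted over the list alone; list adjusted p = 0.01, adjusted p = 0.31 with an estimated correlation), but not as a list in epiHybrid 92 (list adjusted p = 0.191). QQS was at 1.2 ± 0.104 FPKM in epiHybrid 92, below Col-wt, and at 41.3 ± 18, 59.4 ± 14.2 and 53.5 ± 1.17 in epiHybrids 150, 193 and 232, above it. The genes of DNA methylation were lower as a list in all 4 epiHybrids (list adjusted p = 0.000172, 0.00275, 0.000335 and 0.00795 in epiHybrids 92, 150, 193 and 232; adjusted p = 0.546, 0.534, 0.352 and 0.488 with an estimated correlation), with medians of -0.4, -0.21, -0.16 and -0.25. Limma called 6, 2, 0 and 1 members (6 at an unadjusted p under 0.05 in epiHybrid 193), and 8, 3, 0 and 0 adjusted over the list alone. Floral organ markers were higher as a list in epiHybrid 232 (1 called, 6 adjusted over the list alone; list adjusted p = 0.0228, adjusted p = 0.575 with an estimated correlation and 0.0803 with the axis score as a covariate). Jasmonate genes were lower as a list in epiHybrid 92 (1 called, 0 adjusted over the list alone; list adjusted p = 0.0283, adjusted p = 0.794 with an estimated correlation and 0.288 with the axis score as a covariate).

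With the 11 epiHybrid libraries pooled against Col-wt, limma called 3382 entries, 2257 higher and 1125 lower. COR15A, COR15B and GOLS3 rose with log2 changes of 3.01 (SE 0.45), 1.87 (SE 0.28) and 1.55 (SE 0.26). Of the list, 10 of the 13 cold and dehydration genes were called higher (11 higher and 1 lower adjusted over the list alone; list adjusted p = 7.6e-05, adjusted p = 0.177 with an estimated correlation). LHCB2.3 and PORC rose, and FLC, PR1, PR2, PR5, FMO1, MAM3 and SAG13 fell. Salicylic acid defence was lower (7 called, 10 adjusted over the list alone; list adjusted p = 1.06e-06, adjusted p = 0.361 with an estimated correlation). DNA methylation (6 lower, 6 adjusted over the list alone; list adjusted p = 0.000127, adjusted p = 0.289 with an estimated correlation) and glucosinolate synthesis (3 lower, 3 adjusted over the list alone; list adjusted p = 0.008, adjusted p = 0.694 with an estimated correlation) were lower. Loci silenced by methylation (6 higher, 6 higher and 1 lower adjusted over the list alone; list adjusted p = 0.000448, adjusted p = 0.0746 with an estimated correlation) and light harvesting (3 higher, 3 adjusted over the list alone; list adjusted p = 0.0212, adjusted p = 0.788 with an estimated correlation) were higher. Without Col-wt replicate 1, 2 or 3 the count was 1544, 1483 or 5114.

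**Figure D4:**
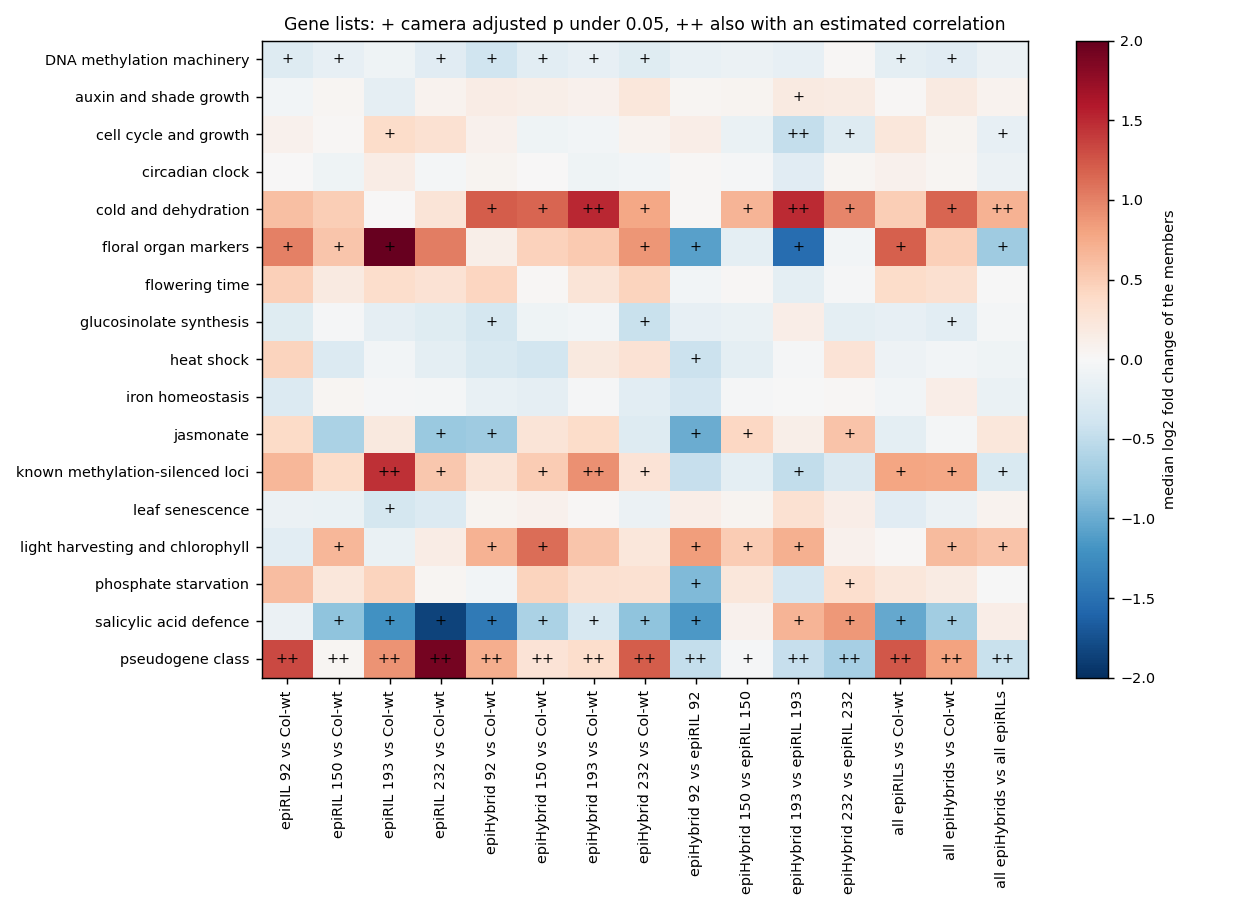
Colours give the median log2 fold change of each of 17 gene lists (rows) in 15 comparisons (columns), with + where the list passed the test and ++ where it also passed with an estimated correlation. Salicylic acid defence lies below 0 against Col-wt and cold and dehydration above 0 in the epiHybrids.

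Each epiHybrid was compared with its own epiRIL to ask what the wild-type genome of the cross changed. Entries of the pseudogene class fell in 3 of the 4 lines and rose as well as fell in line 150. The pseudogene class had 250 entries lower and 1 higher in epiHybrid 92, 352 and 3 in epiHybrid 193, and 347 and 1 in epiHybrid 232, but 98 lower and 67 higher in epiHybrid 150 (class adjusted p = 0.0122, 0.0139, 0.00038 and 0.807 in this order with an estimated correlation). VANA21 fell by 0.9 on the log2 scale (SE 0.17, adjusted p = 0.00286) in epiHybrid 193 and by 0.99 (SE 0.17, adjusted p = 0.00288) in epiHybrid 150, and CAC1 by 0.86 (SE 0.1, adjusted p = 5.08e-05) in epiHybrid 232. AT2G04320 (chromosome 2, 1395257 to 1629535), a pseudogene listed at 0 in Col-wt, fell from 154 ± 40.2 to 11.7 ± 7.68 FPKM in epiHybrid 232. With the compared pair of groups alone in the fit, VANA21 and AT2G04320 were no longer called.

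Limma called 529 entries in line 92 (103 higher, 426 lower), 307 in line 150 (132, 175), 1357 in line 193 (404, 953) and 846 in line 232 (179, 667). In line 92 the count was 211 without epiHybrid replicate 2 and 255 or 242 without epiRIL replicate 1 or 2. It was 493 in line 150 without epiHybrid replicate 3. In line 193 it was 856 without epiHybrid replicate 2 and 716 or 779 without epiRIL replicate 2 or 3, and in line 232 it was 484 without epiHybrid replicate 2 and 403 or 304 without epiRIL replicate 1 or 2. With only the compared groups in the fit, 9 entries were called in line 92, 47 in line 150 and 120 in line 193, but 1155 in line 232.

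Line 150 stood apart at a stretch of chromosome 3. QQS rose from 1.13 ± 0.72 FPKM in epiRIL 150 to 41.3 ± 18 in epiHybrid 150 (n = 3 each), a log2 change of 4.3 ± 0.32 (SE, adjusted p = 8.13e-08). AT3G32020 (chromosome 3, 12992006 to 12992614, a pseudogene with more than 1 entry of its name) rose from a listed 0 to 677 ± 529. XLOC_019673 (chromosome 3, 14788887 to 14791570) rose from 1.14 ± 1.14 to 793 ± 725 FPKM. In the opposite direction XLOC_007485 (chromosome 1, 23306534 to 23509502) stood at 37 ± 16.9 FPKM in epiRIL 150 and was listed at 0 in epiHybrid 150 and Col-wt. Active in epiHybrid 150 and in neither parent were 34 entries, all on chromosome 3, with 90% of them between 11569820 and 15504551, against 3, 2 and 3 entries in lines 92, 193 and 232. Of all 1158 entries active in any epiRIL or epiHybrid, 21.0% lay on chromosome 3 (10000 permutations, p = 0.0001, the smallest they can give). Their median was 5.2, 2.25 and 2.31 FPKM in the 3 epiHybrid 150 libraries and 0 in all 3 of epiRIL 150. All 34 were active in another epiRIL.

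In line 193 several groups of genes differed between epiHybrid and epiRIL. Of the cold and dehydration genes 9 of 13 rose (10 adjusted over the list alone; list adjusted p = 1.89e-11, adjusted p = 0.0139 with an estimated correlation), with RD29A at 169 ± 61.3 against 39.2 ± 10.7 FPKM, COR15B at 813 ± 166 against 229 ± 40.5 and GOLS3 at 13.4 ± 4.25 against 3.02 ± 1.17 (n = 3 each). Cell cycle and growth genes fell (7 of 21, with 10 lower and 2 higher adjusted over the list alone; list adjusted p = 4.15e-05, adjusted p = 0.0359 with an estimated correlation), with CYCB1;2 at 7 ± 1.49 against 12.1 ± 0.495 FPKM. Floral organ markers fell (6 of 7, with 7 adjusted over the list alone; list adjusted p = 1.62e-06, adjusted p = 0.133 with an estimated correlation), with AG at 0.888 ± 0.201 against 2.71 ± 0.395 and SEP2 at 0.858 ± 1.09 against 3.9 ± 1.14. The repressors of flowering MAF4 (an entry joined with AT5G65080) and FLM rose from 1.02 ± 0.166 to 5.5 ± 2.06 and from 12.5 ± 4.3 to 44.4 ± 16.4 FPKM, and MAM3 rose from 2.82 ± 0.409 to 7.34 ± 1.94. With the compared pair of groups alone in the fit, limma still called COR15B and no longer RD29A, GOLS3, CYCB1;2, AG, SEP2, MAF4, FLM or MAM3. Loci silenced by methylation fell (3 of 8, 5 adjusted over the list alone; list adjusted p = 0.00152, adjusted p = 0.071 with an estimated correlation). Auxin and shade growth genes rose (3 of 8, 4 adjusted over the list alone; list adjusted p = 0.0395, adjusted p = 0.339 with an estimated correlation). Salicylic acid defence was higher as a list (0 called by limma, 7 at an unadjusted p under 0.05 and 5 adjusted over the list alone; list adjusted p = 2.29e-05, adjusted p = 0.339 with an estimated correlation). Light harvesting was higher as a list (0 called by limma, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone; list adjusted p = 0.00041, adjusted p = 0.459 with an estimated correlation).

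Defence genes were lower as a list in epiHybrid 92 and higher in epiHybrid 232 than in their epiRILs, and the difference between the lines was not tested for this list. In line 92 limma called 3 of 19 lower (7 adjusted over the list alone; list adjusted p = 4.65e-08, adjusted p = 0.402 with an estimated correlation). In line 232 it called 2 higher (4 adjusted over the list alone; list adjusted p = 3.42e-08, adjusted p = 0.318 with an estimated correlation). In line 92 TOC1 fell from 28.8 ± 0.812 to 15.4 ± 2.21 FPKM, and AT1G02820 (chromosome 1, 623765 to 624475) and AT5G48490 (chromosome 5, 19647835 to 19648281) rose from 3.25 ± 0.0727 to 23.8 ± 9.82 and from 16 ± 0.685 to 81.4 ± 24.4 (n = 2 each). None of these 3 calls held with only the pair of groups in the fit. Line 92 also had 5 lists that passed with 0 members called by limma. Light harvesting was higher (6 at an unadjusted p under 0.05, 5 adjusted over the list alone; list adjusted p = 4.65e-08, adjusted p = 0.402 with an estimated correlation). Floral organ markers, jasmonate, phosphate starvation and heat shock genes were lower (3, 4, 3 and 2 at an unadjusted p under 0.05, 0 adjusted over the list alone in each; list adjusted p = 0.00739, 0.00666, 0.00187 and 0.0328; adjusted p = 0.497, 0.675, 0.402 and 0.485 with an estimated correlation). In line 232 the cold and dehydration genes were higher (1 called, 3 adjusted over the list alone; list adjusted p = 2.29e-06, adjusted p = 0.123 with an estimated correlation). Jasmonate and phosphate starvation were higher and cell cycle lower there with 0 called by limma, 2, 3 and 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.0143, 0.0143 and 0.014; adjusted p = 0.762, 0.478 and 0.284 with an estimated correlation). In line 150 the cold and dehydration genes were higher (2 called, 6 adjusted over the list alone; list adjusted p = 1.28e-05, adjusted p = 0.279 with an estimated correlation). There the jasmonate and light harvesting lists were higher with 0 members called by limma and 0 adjusted over the list alone, 2 jasmonate genes higher and 1 light harvesting gene lower at an unadjusted p under 0.05 (list adjusted p = 0.0137 and 0.00732; adjusted p = 0.807 for both with an estimated correlation, and 0.127 for jasmonate with the axis score as a covariate). The light harvesting genes had a median of 0.5 but a mean of -0.01. The 14 flowering time genes passed as a list in no comparison (lowest adjusted p 0.218).

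With all epiHybrids taken against all epiRILs, limma called 2183 entries, 634 higher and 1549 lower, and the pseudogene class held 557 of the lower and 11 of the higher ones (class adjusted p = 0.000552 with an estimated correlation). VANA21, VANC21 and AtMu1 fell by 0.76, 0.38 and 0.56 on the log2 scale, and ANT, CYCB1;2, VSP1 and MYB28 fell. AT1G69140 (chromosome 1, 25991520 to 25991872), a transcribed pseudogene, rose by 2.96 (SE 0.4, adjusted p = 5.63e-05), with 40.4, 111, 97.4 and 41.6 FPKM in epiHybrids 92, 150, 193 and 232 against 7.43, 12.6, 3.41 and 9.88 in their epiRILs. COR15A, COR15B, RD29A, GOLS3, PIF4, IAA29, MAF4, FLM and BNS rose over the pooled libraries, though the means of RD29A in line 92, FLM in line 150 and GOLS3 in line 232 were lower in the epiHybrid (78.6 against 94.4, 34.9 against 35.7 and 6.04 against 6.08 FPKM). In line 193 the mean of BNS was lower in the epiHybrid too. QQS was called higher over the pooled libraries (log2 change 0.78, adjusted p = 0.00619) but did not go the same way in all lines. Its mean was above that of the epiRIL in epiHybrids 92 (1.2 against 0.372 FPKM, not called) and 150 (called), and below it in epiHybrids 193 and 232 (59.4 against 125 and 53.5 against 95.7, neither called). BNS, which encodes a subunit of the anaphase-promoting complex, stood between 23.9 and 26.9 FPKM in the epiHybrids and 23.7 ± 6.87 in Col-wt, against 9.85, 15.4, 28.6 and 11.6 in epiRILs 92, 150, 193 and 232. Of the cold and dehydration genes 8 rose (11 adjusted over the list alone; list adjusted p = 9.64e-10, adjusted p = 0.0263 with an estimated correlation). Floral organ markers were lower (4 called, 7 adjusted over the list alone; list adjusted p = 0.000485, adjusted p = 0.292 with an estimated correlation), as were cell cycle genes (4 called, 7 adjusted over the list alone; list adjusted p = 0.0144, adjusted p = 0.28 with an estimated correlation). Loci silenced by methylation were lower as a list (5 lower and 2 higher, 6 and 2 adjusted over the list alone; list adjusted p = 0.0333, adjusted p = 0.28 with an estimated correlation). Light harvesting genes were higher as a list (1 called, 0 adjusted over the list alone; list adjusted p = 1.49e-06, adjusted p = 0.292 with an estimated correlation). Without epiRIL 92 replicate 1 or epiRIL 232 replicate 2 the count was 1417 or 1454. With the 4 line means as replicates, paired by line, limma called 0 entries (3522 at an unadjusted p under 0.05, smallest adjusted p 0.176).

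Each epiHybrid was finally compared with the arithmetic mean of its parents, to ask where it left the middle between them. Its position was taken from entries changed in the epiRIL. Among entries called in an epiRIL with a log2 change of at least 1, the epiHybrid lay at a median of 0.48 of the way from Col-wt to the epiRIL in line 92 (quartiles 0.35 and 0.64, 1005 entries), 0.55 in line 150 (0.42 and 0.7, 626), 0.38 in line 193 (0.25 and 0.52, 1090) and 0.52 in line 232 (0.4 and 0.71, 2049). For the pseudogene class the medians were 0.44, 0.53, 0.37 and 0.48. Entries lower in the epiRIL lay nearer to it, at 0.9 (49 entries), 0.8 (67), 0.55 (206) and 0.71 (639). The same Col-wt libraries served to choose the entries and to place the epiHybrid. An entry chosen because its Col-wt value was high by error is placed too near the epiRIL, and how much this adds was not tested. IRE1B stood at 2.51 ± 0.599 FPKM (n = 2) in epiHybrid 92 and MRD1 at 21.9 ± 5.4 (n = 3) in epiHybrid 193, both between their parents.

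FLC was called below the mid-parent in all 4 lines with the settings used throughout, and part of the cold genes above it in lines 150, 193 and 232. Log2 differences of FLC were -0.86, -0.94, -0.75 and -0.74 in lines 92, 150, 193 and 232 (adjusted p = 0.00583, 0.000289, 0.00704 and 0.0166). In line 92 its adjusted p was 0.0983 without epiHybrid replicate 2, and in line 232 it was 0.053 and 0.101 without epiHybrid replicate 1 and 3, 0.0528 without epiRIL replicate 1 and 0.064 without Col-wt replicate 1. With a pseudocount of 0.1 the call held in line 150 (adjusted p = 0.0111) and was lost in lines 92, 193 and 232 (adjusted p = 0.0529, 0.117 and 0.193). With only the compared groups in the fit it was lost in the same 3 lines (adjusted p = 0.1, 0.0569 and 0.127). The lowest adjusted p over all alternatives was 0.00214, 0.000131, 0.00189 and 0.000652 in lines 92, 150, 193 and 232. COR15B and RD29A lay above it by 1.79 (SE 0.3, adjusted p = 0.00304) and 1.16 (SE 0.24, adjusted p = 0.0153) in epiHybrid 150 and by 2.02 (SE 0.3, adjusted p = 0.00237) and 1.7 (SE 0.24, adjusted p = 0.00113) in epiHybrid 193, as did QQS by 2.81 (SE 0.29, adjusted p = 8.1e-06) in epiHybrid 150. Limma called 0, 3, 6 and 2 cold and dehydration genes above the mid-parent in lines 92, 150, 193 and 232 (2, 10, 11 and 8 adjusted over the list alone), with 3 at an unadjusted p under 0.05 in line 92. With only the compared groups in the fit, COR15B in lines 150 and 193 and TOC1 in line 92 were no longer called, and with array weights RD29A in line 150 was not. The unnamed XLOC_027815 (chromosome 5, 10817143 to 10820650) stood at 25 ± 6.56 FPKM in epiHybrid 193, 1.74 ± 0.633 in its epiRIL and 0.0659 ± 0.114 in Col-wt. In line 92 TOC1 lay below it, at -0.88 ± 0.1 on the log2 scale (SE, adjusted p = 8.3e-05). Over all lines COR15A, COR15B, GOLS3, RD29A, LHCB2.3, PORC, PIF4 and AT1G69140 lay above the mid-parents and CMT3, a plant-specific DNA methyltransferase, MYB28 and FLC below. There 10 cold and dehydration genes lay above and 4 DNA methylation genes below (11 and 7 adjusted over the list alone).

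The difference from the mid-parent was called by limma with a delta-method error for 713 entries in line 92 (387 above, 326 below), 247 in line 150 (182, 65), 275 in line 193 (148, 127), 76 in line 232 (35, 41) and 1761 over all lines (888, 873). With a mid-parent on the log2 scale more of the calls lay above it: 883 above and 437 below in line 92, 474 and 89 in line 150, 440 and 127 in line 193, 498 and 56 in line 232 and 1535 and 897 over all lines. These counts moved with single libraries. In line 92 the count was 41 without epiHybrid replicate 2 and 1241 without its replicate 1, 177 or 174 without epiRIL replicate 1 or 2, and 291, 271 or 2049 without Col-wt replicate 1, 2 or 3. In line 150 it was 132 or 1007 without epiHybrid replicate 1 or 3. In line 193 it was 126 or 102 without epiHybrid replicate 2 or 3, 536, 128 or 125 without epiRIL replicate 1, 2 or 3, and 165 or 131 without Col-wt replicate 1 or 2. In line 232 it was 41, 29 or 46 without epiHybrid replicate 1, 2 or 3, 17 or 27 without epiRIL replicate 1 or 2, and 33, 30 or 153 without Col-wt replicate 1, 2 or 3. Over all lines it was 805 without epiHybrid 92 replicate 2, 1082 or 1173 without epiHybrid 232 replicate 2 or 3, 1156 without epiRIL 92 replicate 1 and 604 or 601 without Col-wt replicate 1 or 2.

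Comparisons with the same 3 Col-wt libraries shared calls. epiRILs 92 and 232 called 928 entries higher in both, against 110 for independent lists and 0 for simulated unchanged groups, with a covariance of fold changes of 0.627 against 0.055 simulated. epiRILs 92 and 150 shared 522 (independent 41, simulated 0; covariance 0.353 against 0.055) and epiRILs 150 and 193 shared 300 (independent 45.5, simulated 0; covariance 0.238 against 0.055). For this last pair the correlation of fold changes, 0.43, was below the simulated 0.5. An epiRIL and its own epiHybrid shared 895, 610, 613 and 1384 higher calls in lines 92, 150, 193 and 232. Splitting the 3 controls would leave a part with 1 library, so part of these overlaps may come from the shared controls. The simulation drew entries independently, without the axis along which libraries of a group differ. Its values therefore do not bound the overlap that shared controls can give. The authors' deposited table marks 2572, 1493, 2757 and 3898 entries as significant for epiRILs 92, 150, 193 and 232 against Col-wt, 3527, 1636, 1589 and 3359 for the epiHybrids against Col-wt and 1098, 743, 1564 and 1122 for the epiHybrids against their epiRILs. Of the limma calls, between 48.5% and 57.0% were also significant there, all in the same direction.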

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

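The tests of the axis as a covariate, of gene length on the axis and of a chromosome block in epiHybrid 150, the shares at matched level for a mixture, the bounds applied to the share of higher calls and to the clock genes, and the composition of the highest splits were chosen only after the result was seen.

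The effect of a line differed between lines in a limma test of the difference itself (adjusted p under 0.05), which called entries in all 18 comparisons of a pair of lines. Between epiRILs against Col-wt it called 1512 entries for lines 150 and 193, 1182 for 150 and 232, 1060 for 193 and 232, 753 for 92 and 150, 1082 for 92 and 193 and 1024 for 92 and 232. Between epiHybrids against Col-wt it called 638, 796, 683, 896, 993 and 534 for the same pairs in this order. For an epiHybrid against its epiRIL it called 425, 303, 240, 270, 537 and 604.

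The 34 entries active in epiHybrid 150 and in neither parent all lay on chromosome 3. Libraries from another epiRIL are argued against, since epiHybrid 150 had 58.6% of active entries in common with epiRIL 150 and at most 30.1% with another. A mixture with RNA of another line is argued against too: of the entries active in epiRIL 232 or 193 and in neither parent, 7.26% of 441 and 11.8% of 279 were active in epiHybrid 150, and 12.8% of 125 and 21.8% of 78 at or above the median level in that epiRIL of the members of the 34 active there. A candidate is a block of chromosome 3, where all 34 entries lay, that differs between the epiRIL 150 plants sampled and the plant crossed. That test was made on the data that raised it, and plants were not genotyped here.

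More entries were higher than lower for all epiRILs vs Col-wt (72.9% of calls), but the balance moved with the weight of single libraries: 7247 were higher and 5777 lower with array weights, and 3290 and 2046 without Col-wt replicate 3. The axis and the annotated pseudogene class are each argued against as the whole cause. The share was 66.2% with the axis score as a covariate and 63.1% (95% Wilson interval 60.9 to 65.2, 1986 calls) without the class. Lower detection in the Col-wt libraries cannot be told apart from a real excess, since among the 846 calls of at least 10 FPKM on average the share was 60.5% (57.2 to 63.8), past the bound set beforehand by less than its interval, and depth is unknown. Both restrictions at once left 55.3% of 745 calls higher. Named entries outside the class had 758 higher and 599 lower calls, and release of silenced genes outside it was not tested.

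Libraries of a group separated along an axis with jasmonate and light harvesting genes at 1 end. Gene length bias is argued against (Spearman rho 0.012 across entries, which are not independent). A different time of day at harvest cannot be told apart from other causes: the mean slopes of 3 morning and 5 evening clock genes were -0.27 and -0.026, a difference of 0.244 (SE 0.14), which is under the bound set beforehand by less than its error. Library batches and differences between plants stay open, as the labels give neither.

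For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In epiRIL 150 against Col-wt 1 split reached the real count (911, highest other 2), as in epiHybrid 150 (1510, 2), epiHybrid 232 (2210, 1), epiHybrid 150 against its epiRIL (307, 45) and epiHybrid 193 against its epiRIL (1357, 2). In epiRIL 193 against Col-wt it was 2 splits (1665, 2112) and in epiHybrid 193 against Col-wt 2 (888, 4640). The split with 2112 calls put epiRIL 193 replicate 1 with Col-wt replicates 1 and 2, and the one with 4640 put epiHybrid 193 replicate 2 with them. Their sides differed by 2.01 and 2.09 in axis score, against 0.81 and 0.03 for the real groups, so they point to a structure of the samples along that axis.

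The 100 splits exchange libraries whatever their line, so they bear only on a chance division of libraries. Few splits, the real one included, reached the real count for all epiRILs against Col-wt (1 split, 2712 calls, highest other 1371) and all epiHybrids against all epiRILs (1 split, 2183, 68). The same held for all epiHybrids against the mid-parents (3 splits, 1761, 5048). The exchange adds differences between lines to the spread within groups, which can lower the counts of other splits. Chance is therefore not excluded by this measure. The lines themselves were not exchanged: with the 4 line means as replicates, limma called 0 entries between epiHybrids and epiRILs. The count against the mid-parents was 604 or 601 without Col-wt replicate 1 or 2, and that for the epiRILs 1597 or 1547. More splits reached the real count for all epiHybrids against Col-wt (7 splits, 3382, 7590), where chance is not excluded either. The same holds for the mid-parent comparisons of epiHybrid 150 (6 splits, 247, 1331) and epiHybrid 193 (7 splits, 275, 2456). Splits with several times the real count, such as 2456 against 275 or 5048 against 1761, point to a structure of the samples.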

How the results depend on the processing

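The axis covariate, the summed entries and the fit without mitochondrial and plastid entries were chosen only after the data were seen, as was the method for array weights. Rescaling (factors 1.001 to 1.032) and summed entries moved no count of calls by more than 1.5 times. Leaving out organelle entries was run for 15 counts, those against Col-wt or a mid-parent, and moved none of these by more than 1.5 times. The excess of neighbouring calls kept direction and side of the threshold in all 8 comparisons with Col-wt when pairs lay within 100 kb or calls also had a log2 change of at least 1. Where a count or call changed, the cause was not tested, except that no filter tests more entries (29171), leaving out a library or fitting only the compared groups uses fewer libraries, and the axis comes from the same residuals, so its fit makes calls too easily. The axis score also holds differences between groups, so the covariate can remove part of a comparison too. Depth is unknown, so what it limits cannot be stated. A group left with 1 library is assumed to vary like the others.

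With 1 library left out in turn, counts ranged as follows. epiRIL 92 vs Col-wt 975 to 2125, epiRIL 150 vs Col-wt 679 to 1275, epiRIL 193 vs Col-wt 1048 to 3394, epiRIL 232 vs Col-wt 1754 to 5850. epiHybrid 92 vs Col-wt 952 to 5555, epiHybrid 150 vs Col-wt 867 to 2733, epiHybrid 193 vs Col-wt 651 to 1387, epiHybrid 232 vs Col-wt 1345 to 4688. Against its epiRIL 211 to 720, 223 to 493, 716 to 1550 and 304 to 798 (lines 92, 150, 193, 232), against the mid-parent 41 to 2049, 132 to 1007, 102 to 536 and 17 to 153. Pooled, 1547 to 5336 (epiRILs), 1483 to 5114 (epiHybrids), 1417 to 2951 (against each other) and 601 to 2620 (mid-parents). Calls of named genes were refitted 4756 times in this way and were lost in 1006 of these fits, and 10 fits gained a call.

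With a pseudocount of 0.1, epiHybrid 92 against epiRIL 92 had 347 calls, epiHybrid 232 against epiRIL 232 496 and epiHybrid 232 against its mid-parent 32, and the odds ratio of the pseudogene class among lower calls of epiHybrid 193 was 0.237 (two-sided Fisher's exact p = 0.195). Without the filter the counts for epiHybrid 92 against epiRIL 92 and epiHybrid 232 against its mid-parent were 796 and 185. With only the compared groups in the fit, epiRILs 193 and 232 had 1031 and 2015 calls, epiHybrids 92 and 150 986 and 529, the epiHybrids of lines 92, 150 and 193 against their epiRILs 9, 47 and 120 and against the mid-parent 70, 135 and 80, and of 336 calls of named genes 184 were lost and 152 kept. With a mid-parent on the log2 scale, counts were 1320, 563, 567 and 554 in lines 92, 150, 193 and 232. With line means as replicates, limma called 0 of the pooled epiHybrid against epiRIL differences (3522 at an unadjusted p under 0.05).

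With array weights (0.131 for epiHybrid 150 replicate 1 to 2.89 for epiHybrid 193 replicate 1, 0.204 for Col-wt replicate 3) every count moved: 10961, 5308, 12976 and 13050 for epiRILs 92, 150, 193 and 232 against Col-wt, 8967, 2998, 9122 and 12217 for the epiHybrids, 1647, 716, 6081 and 4629 against their epiRILs, 4129, 400, 4434 and 6058 against mid-parents and 13024, 11592, 5126 and 7594 pooled.

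By correlation over all entries, replicate numbers did not clearly pair the libraries: 26 of 87 same-number pairs had correlated deviations above 0.1 (median 0.025, other pairs -0.014), and 10 of 24 libraries correlated best with their own number. Replicate 3 had the lowest axis score in 5 of the 6 groups of 3 libraries, so a structure shared by replicate number stays open. With the replicate block the counts were 2448 for epiRIL 92 vs Col-wt, 6209 for epiRIL 232 vs Col-wt, 6010 for epiHybrid 92 vs Col-wt, 1774 for epiHybrid 92 vs mid-parent and 4595 for all epiRILs vs Col-wt, the other 15 within 1.5 times. Of the lists, cold and dehydration (adjusted p = 0.0542 from camera in limma) and light harvesting (0.21) did not pass in epiHybrid 92 with the block, and 5 list tests passed only with it.

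With the axis score as a covariate, counts were 1778 for epiRIL 150, 5585, 3146 and 2044 for epiHybrids 92, 150 and 193, 1603, 500, 2516 and 1929 for lines 92, 150, 193 and 232 against their epiRILs, 3624, 679, 1533 and 357 against mid-parents, and 6388, 3813 and 5423 for the pooled epiHybrids against Col-wt, epiRILs and mid-parents. Light harvesting in all epiRILs turned from lower (adjusted p = 0.828 from camera in limma) to higher (adjusted p = 0.000835). Of 255 list tests 78 passed with and without the covariate, and 20 with an estimated correlation.

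Summing entries of the same name turned 11 calls, as the sum adds the other entries of the name: PRP4 to 0.31 in epiRIL 150, 0.24 in epiHybrid 193, 0.76 against epiRIL 193, 0.47 against that mid-parent, 0.27 in all epiHybrids and 0.41 against all mid-parents, PSBT to 0.52, 0.72 and 0.42 in epiHybrids 92, 150 and all, and AT5G49440 to 0.11 and 0.22 in epiHybrid 193 against Col-wt and the mid-parent (log2). On the log scale, the epiHybrid lay at 0.7, 0.73 and 0.54 of the way to the epiRIL in lines 92, 150 and 193.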

Other observations

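The tests of the entries listed at 0 and of entries beyond both parents were chosen only after the result was seen.

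Single loci were at different levels in different lines, and the values were compared without a test. IRE1B, near 0 in epiRIL 92, stood between 6.48 and 7.54 FPKM in the groups of the other lines, and MRD1, near 0 in epiRIL 193, between 34.5 and 44.6. JAL5 stood at 13.8 FPKM in Col-wt and at 0.753, 0.875, 17.7 and 1.73 in epiRILs 92, 150, 193 and 232, and its epiHybrids stood at 0.714, 0.881, 15.4 and 3.27. These comparisons between lines were picked after the values were seen.

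Of the entries that limma called in the epiHybrid against Col-wt and also against its epiRIL, 79, 116, 80 and 17 lay above both parents in lines 92, 150, 193 and 232, 24, 1, 21 and 7 below both and 324, 136, 432 and 585 between them. Entries with a median of at least 5 FPKM in the other groups were listed at 0 in all Col-wt libraries in 104 cases, against 0 to 40 cases for the other groups treated alike. Among the pseudogene class this was 40 of 183 (21.9%) and among protein-coding entries 19 of 10391 (0.183%).

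A hypothesis is that the entries of the pseudogene class silent in Col-wt and expressed in the lines may lie in blocks of chromosome inherited from the ddm1 parent. It predicts that called neighbours within the class go together. In 4 of 4 epiRILs the class had more neighbouring pairs than 95% of permutations, which fits such blocks. Methylation was not analysed here.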
